A study of Mus musculus with 14 samples.

How the data were processed

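RNA from the liver of 14 C57BL/6 mice was measured, 7 wild type and 7 with the genotype that the labels write as mthr-/-. The labels do not spell this abbreviation out. They give liver as the tissue and primary hepatocytes as the cell type, and they number the animals of each genotype, so each array stands for 1 animal. Per the labels' protocols, betaine was added to the drinking water of the homozygous animals only, so genotype and betaine cannot be told apart here. The wild type group holds 2 females and 5 males, and the mthr-/- group 4 females and 3 males. The labels also name 4 slide series, called A to D here. Series A holds 1 wild type and 4 mthr-/- arrays, series B 4 wild type and 2 mthr-/- arrays, series C 2 wild type arrays and series D 1 mthr-/- array. Since series C and D each hold 1 genotype, a fit with slide series as a block takes the genotype difference from series A and B alone.

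Per the labels' protocols, total RNA was copied into cDNA from oligo-dT primers with a single fluorescent nucleotide, so each array has 1 colour. The deposited array files hold, per the file headers, the intensity of each spot and of its local background on a linear scale, for 4 spots of every oligonucleotide, with further columns that the authors scaled. The scanner, the image software and the settings are not given in the sources used here. Some cells of the scaled columns are blank, and the spots concerned were taken as blanked by the authors. On array mthr-/- 1 the values of block 3 repeat those of block 2 and were counted once. One array file has a shifted header and another lists its positions in descending order, and both were read by array index. The deposited value table holds intensity values of the same arrays for 103 oligonucleotides. Set against the array files, its values equal the authors' mean of the scaled background-subtracted spots within 1 intensity unit for 12 arrays. For wild type 5, 89 of 102 values differ by more than that, and for mthr-/- 7, 79 of 103. The comparison shows a linear scale without centring of genes, and how the values of those 2 arrays were made stays unknown. Its medians for wild type 1 to 7 are 50, 45.5, 41.8, 40.8, 46.7, 32.8 and 42.2. Those for mthr-/- 1 to 7 are 47.3, 54.6, 69.4, 67.1, 44.6, 51.0 and 38.4. A table of the authors' own comparison gives, per the file headers, the median intensity of each genotype and the log10 of the mthr-/- median over the wild type median. Its wild type medians equal the median of the 7 arrays in the value table for 100% of the oligonucleotides, within 0.01 intensity units. Its mthr-/- medians equal the median of the 6 arrays other than mthr-/- 7 for 99.0%, and the median of all 7 for 0.971%.

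Spots were corrected with the normexp method of limma 3.58.1 in R 4.3.3 with an offset of 50, which draws the log2 differences of dim genes towards 0. Arrays were then quantile normalized, control spots and blanked spots were left out, and the spots of an oligonucleotide were averaged on the log2 scale. An oligonucleotide entered the tests when it was above background on at least 7 of the 14 arrays. The files give neither a background SD nor a detection mark, so the limit was the mean plus 2 SD of background-subtracted intensity over the 16 spots of 4 plant control oligonucleotides on the same array. It ran from -0.21 on wild type 2 to 9.81 on wild type 6, so on wild type 2 slightly negative intensities counted as above background. That limit was chosen over a median-based one before any test was run. Of 284 mouse oligonucleotides, 139 passed. A gene with several was represented by the brightest, which left 134 of the 272 different genes. Gene names came from a reference table of RefSeq names through the accession for 193 oligonucleotides, through the symbol for 51 and through an older synonym for 19, and 21 kept the name in the files. No genome was used, so positions of genes are not given. No per-sample column was left unmapped.

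Genotype was tested with limma (lmFit and eBayes, two-sided) on all 14 arrays without covariates, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The sexes were compared with genotype in the model, and a genotype by sex term tested whether the genotype difference depends on sex. Gene lists with at least 3 tested genes were tested with fry, whose directional p asks whether the genes of a list move one way on balance without comparing them with other genes. Of 23 lists fixed in advance, 12 had enough tested genes. The samples, the lists, the tests and the rule for named genes were fixed before the data were examined. By that rule, with fewer than 5 genes past the threshold, the 8 higher and 8 lower genes with the smallest p are named, with every tested gene of the one-carbon and osmolyte lists and the 2 genes of smallest p from each other tested list. This gave 46 genes. Results for some genes, among them some that the rule names, are not reported here.

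The procedure was tested on simulated spots made from the means, backgrounds, brightness and spread between animals of these arrays, without any effect of slide series. The SD between spots of an oligonucleotide was set to 0.3 (log2) and not estimated, and genes varied independently of each other. A first version changed 30 of 134 genes and used one spread for all genes. It gave 1.9, 3.9 and 7.8 false calls per run at true log2 changes of 1, 2 and 3, and was then replaced by a version with 20 changed genes and each gene's own spread. In the second version 67.5%, 94.8% and 96.2% of the changed genes were called at those sizes, with 0.9, 1.7 and 2.1 false calls per run. False calls were 6.25%, 8.23% and 9.84% of the calls there, a larger share than a threshold of 0.05 stands for. The median estimate was 0.42, 0.94 and 1.33, below the true sizes, and the steps behind this were not separated. With no changed gene there were 0.15 calls per run.

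Alternatives covered the background correction, the normalization, the filter, the authors' value table, sex and slide series as covariates, single series or sexes, each array left out in turn, array weights and other list tests. Those added after the genotype result had been seen cover the centring of blocks, the blanked spots, array mthr-/- 1 by its first block, an offset of 0 with slide series as a block, and the removal of 3 arrays that stood apart, with and without slide series as a block. Some tests of explanations were also revised after a first result. A test for a lost stretch of array positions first asked for normalized values more than 1 log2 lower. It found 0 of 12 bright oligonucleotides, of which only 2 had room to fall that far, and was replaced by a comparison of spots between blocks. An explanation by a block given in duplicate was replaced by one about blanked spots once the spots had been seen. A test of normalization of a dim array gave no decision when run on wild type 6 and mthr-/- 6 together. It was kept for wild type 6, since mthr-/- 6 was not dim, and Mb was left out. On wild type 6 Mb exceeded the arrays other than these only after normalization, so its removal took out a gene that goes with this explanation. A count of muscle genes by their highest normalized value was 5 of 13, but 5 of the 13 were above background on 0 arrays, and it was replaced by a count of highest intensities among the other 8. A comparison with an offset of 0, set before its result was seen as a test of compression of dim arrays, was dropped: the mthr-/- arrays of series A exceeded the other mthr-/- arrays by 0.63 (SE 0.068) without the offset and 0.39 (SE 0.049) with it. The offset keeps the order of spots within an array, which is what quantile normalization uses, so the order of the arrays was bound to stay (rank correlation 0.996), and a fit with summed intensity as a covariate took its place.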

Results

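Transcript levels were compared in liver, with primary hepatocytes as the stated cell type, between 7 wild type mice and 7 mice of the genotype written mthr-/-. Hepatocytes are the main metabolic cells of the liver. Each animal was measured on 1 single-colour array of spotted oligonucleotides for 272 different genes. Background-subtracted intensity, summed over the mouse oligonucleotides, ran from 14791 to 57034 on the wild type arrays and from 16913 to 87080 on the mthr-/- arrays. Wild type 6 had 70 oligonucleotides above background, and the other arrays had 114 to 186. The limit behind these counts ran from -0.21 on wild type 2 to 9.81 on wild type 6. Wild type 2, the dimmest array at 14791, had 139, so the counts do not rank arrays by signal alone. Correlations between arrays, taken across the 134 tested genes, which are not independent replicates, ran from 0.689 to 0.985, and 0 pairs held identical values. The number of arrays limits the precision, and the median SE of a log2 difference between the genotypes was 0.10. This SE belongs to the scale with an offset of 50, which draws log2 differences of dim genes and their SEs towards 0. In the simulated arrays a true log2 change of 1 had a median estimate of 0.42.

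The first comparison asked which genes differ between mthr-/- and wild type liver. Ahcy, which splits S-adenosylhomocysteine into homocysteine and adenosine, had a log2 normalized intensity of 7.31 ± 0.34 in wild type and 7.85 ± 0.37 in mthr-/- (SD, n = 7 each). The difference was 0.54 (SE 0.18), or 1.45-fold, and 7 of 7 mthr-/- arrays lay above the wild type mean. That mean includes wild type 6 at 6.79, where Ahcy read 1.75, below the limit of 9.81. The groups overlapped: wild type 1, at 7.92, lay above mthr-/- 4, 5, 6 and 7. Mt1, a metal-binding metallothionein, was at 7.55 ± 0.59 in wild type and 8.51 ± 1.04 in mthr-/- (SD, n = 7 each), a difference of 0.96 (SE 0.43). Csad, which makes the taurine precursor hypotaurine, was at 7.64 ± 0.46 and 7.24 ± 0.29 (SD, n = 7 each), a difference of -0.40 (SE 0.20), with 0 of 7 mthr-/- arrays above the wild type mean. These differences did not pass the test: limma called 0 of 134 genes, the smallest adjusted p was 0.579, and 10 genes had an unadjusted p below 0.05, 6 of them higher and 4 lower in mthr-/-.

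The 8 higher genes with the smallest p held 3 enzymes beside Ahcy. Cdo1, which oxidises cysteine on the way to taurine, differed by 0.28 (SE 0.10), Sord, which turns sorbitol into fructose, by 0.33 (SE 0.14), and Sardh, which demethylates sarcosine, by 0.21 (SE 0.10). The others were Mt1, the chaperone gene Hsp90aa1 at 0.094 (SE 0.041), the ribosomal protein gene Rps3a1 at 0.23 (SE 0.10) and the protease inhibitor gene Serpina3n at 0.23 (SE 0.12), which was 0.11 without mthr-/- 4. Sardh was 0.13 without mthr-/- 3. Among the 8 lower genes, Csad aside, the apolipoprotein gene Apoc1 differed by -0.48 (SE 0.23) and the ribosomal protein gene Rps28 by -0.47 (SE 0.21). Further lower were Ctsl, a lysosomal protease, at -0.27 (SE 0.13), Abcc2, an export pump of the bile canaliculus, at -0.11 (SE 0.045), Aifm1, a mitochondrial flavoprotein, at -0.094 (SE 0.050), and Pabpn1, a nuclear poly(A)-binding protein, at -0.064 (SE 0.027). Hsp90aa1, Sardh and Pabpn1 were dim, with median wild type intensities of 4.75, 7.5 and 6. The offset of 50 draws their log2 differences towards 0. With an offset of 0 they were at 0.22 (SE 0.098), 0.46 (SE 0.22) and -0.17 (SE 0.070). For Abcc2, mthr-/- 3 had a background-subtracted intensity of -1890, so local background exceeded its signal. The other mthr-/- arrays averaged 6.86 for Abcc2, against 6.93 in wild type. With slide series as a block these 16 genes kept their sign, and Ahcy was at 0.23 (SE 0.13), Mt1 at 0.64 (SE 0.52), Cdo1 at 0.066 (SE 0.098) and Csad at -0.12 (SE 0.21). Apoc1 shrank to -0.11 (SE 0.26), Rps28 to -0.22 (SE 0.17), Rps3a1 to 0.074 (SE 0.13), Sardh to 0.082 (SE 0.097) and Aifm1 to -0.033 (SE 0.062). Sord at 0.30 (SE 0.18) and Ctsl at -0.26 (SE 0.18) moved little. Within series A and series B the difference was 0.19 and 0.26 for Ahcy, 0.21 and 0.90 for Mt1, and 0.12 and -0.26 for Csad, with 6 of the 8 higher and 5 of the 8 lower genes on the same side in both; series A has 1 wild type array.

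**Figure D1:**
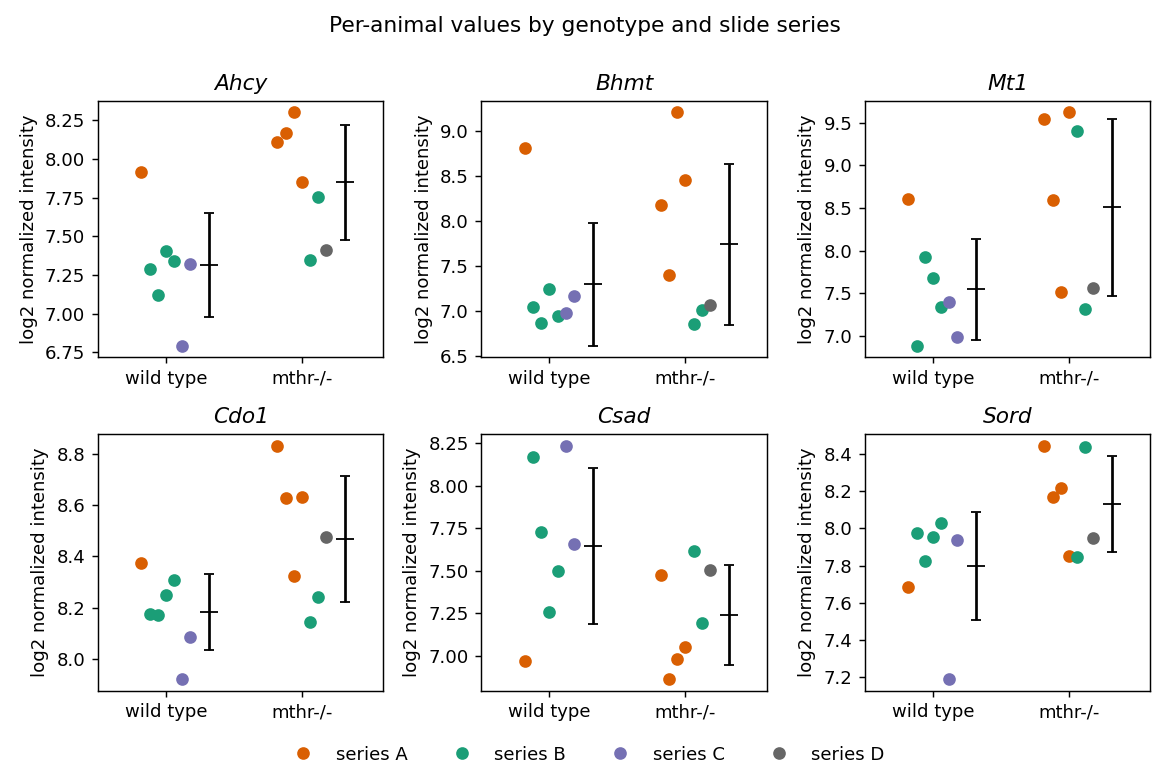
Log2 normalized intensity of 6 genes on the 14 arrays, 7 per genotype, with a dot for each animal coloured by slide series and a bar for the mean ± SD. Ahcy differed by 0.54 and Csad by -0.40 between mthr-/- and wild type, neither past the threshold (Csad is positive without normalization and with reference gene centring), and for Bhmt the dots of series A lie above those of series B in both genotypes.

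The one-carbon list, genes of the methionine cycle and of folate, betaine and choline metabolism, had 14 tested genes. In mthr-/- 10 of them were higher and 4 lower, against 4 higher with arrays centred on their median and 14 higher without normalization. None passed: the counts were 0 over all genes and 0 adjusted over the list alone. Bhmt, which methylates homocysteine from betaine, differed by 0.44 (SE 0.40), and Mat1a, the hepatic S-adenosylmethionine synthase, by 0.41 (SE 0.29). Bhmt was 0.20 without mthr-/- 3 and 0.69 without wild type 1, and Mat1a was 0.18 without wild type 6. Cbs and Cth, which turn homocysteine into cysteine, were at 0.090 (SE 0.12) and 0.12 (SE 0.12), and Gnmt, the glycine methyltransferase, was at 0.023 (SE 0.24). Ahcy, Sardh, Pemt at 0.16 (SE 0.10), Shmt2 at 0.058 (SE 0.054) and Chdh at 0.048 (SE 0.036) were the other higher members, and the lower ones were Chkb at -0.095 (SE 0.078), Shmt1 at -0.080 (SE 0.063), Mat2b at -0.039 (SE 0.072) and Dmgdh at -0.0092 (SE 0.086). Chdh was dim, with a median wild type intensity of 2.75, and was at 0.17 (SE 0.13) with an offset of 0. The list as a whole did not pass fry (adjusted p = 0.372), nor camera with its preset correlation (adjusted p = 0.305) or an estimated one (adjusted p = 0.534). With slide series as a block Bhmt turned to -0.24 (SE 0.29), Mat1a was at 0.033 (SE 0.32), Gnmt stood at 0.34 (SE 0.31) and 12 of 14 genes were higher.

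**Figure D2:**
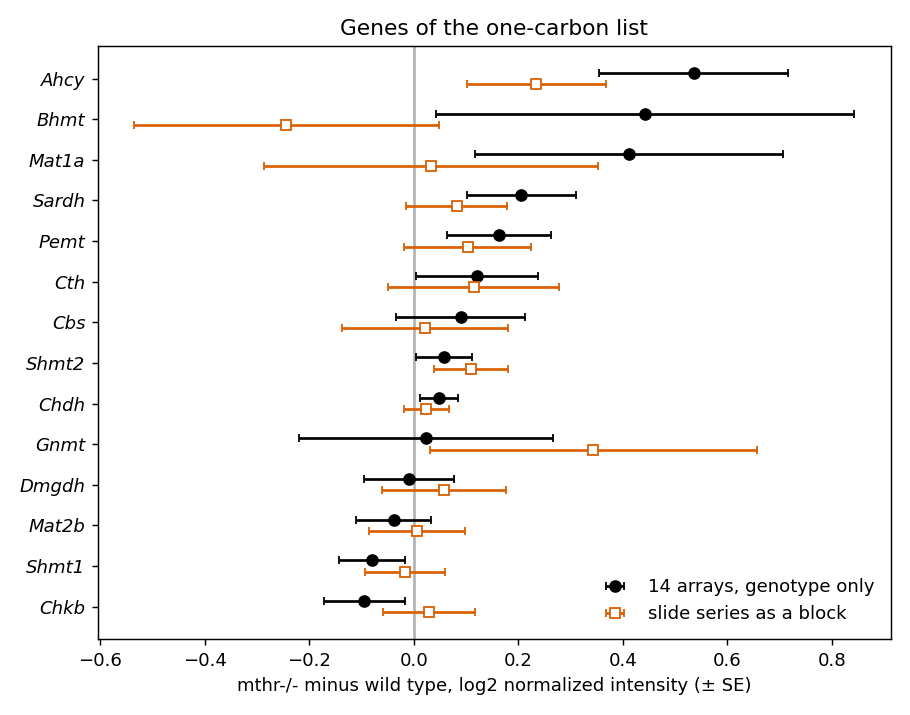
Difference between mthr-/- and wild type in log2 normalized intensity, with its SE, for the 14 genes of the one-carbon list, from all 14 arrays with genotype alone (filled) and with slide series as a block (open). The open differences rest on the arrays of series A and B alone. Ahcy moves from 0.54 to 0.23 and Bhmt from 0.44 to -0.24.

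Genes of osmolyte and water transport showed small differences. The water channel Aqp8, whose kept spots read 0 on mthr-/- 1, was at -0.14 (SE 0.085) and the taurine carrier Slc6a6 at -0.057 (SE 0.075). The 3 higher members were the betaine carrier Slc6a12 at 0.0053 (SE 0.031), the inositol carrier Slc5a3 at 0.015 (SE 0.026) and the water channel Aqp1 at 0.018 (SE 0.037). So 3 of 6 genes were higher. The count was 1 with slide series as a block or without wild type 6, and 6 without normalization or with reference gene centring. The 3 higher members were dim, with median wild type intensities of 2 for Slc6a12, 4.75 for Slc5a3 and 6.75 for Aqp1. The offset draws the log2 differences of such genes towards 0. With an offset of 0 they were at 0.010 (SE 0.087), 0.038 (SE 0.070) and 0.057 (SE 0.093). Their small values therefore do not show unchanged levels. In this list 0 passed the threshold over all genes, 0 passed when adjusted over the list alone, and the list did not pass fry (adjusted p = 0.372, and with slide series as a block adjusted p = 0.186, unadjusted p = 0.0155). In the sulfur list, taurine, cysteine and glutathione metabolism, 2 of 4 genes were higher, 4 without normalization or with reference gene centring, Cdo1 and Csad lay on opposite sides of 0, and 0 genes passed when adjusted over the list alone (fry adjusted p = 0.742).

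Fry called 0 of the 12 lists, with 1 list at an unadjusted p below 0.05, and camera called 0 with its preset correlation, where 1 list was below an unadjusted 0.05, and 0 with an estimated correlation, where none was. The 1 list for fry was oxidative stress defence, where 4 of 5 genes were higher, but 1 with median centring and 2 with cyclic loess (adjusted p = 0.229), led by Mt1 and by the superoxide dismutase gene Sod1 at 0.22 (SE 0.15), or 0.11 without wild type 1. Of 6 genes of protein folding and stress of the endoplasmic reticulum, 5 were higher (adjusted p = 0.372), with Hsp90aa1 and the chaperonin gene Hspe1 at 0.21 (SE 0.12), or 0.12 without mthr-/- 4. Of 7 bile acid and hepatobiliary transport genes 2 were higher, but all 7 without normalization or with reference gene centring (adjusted p = 0.372), Abcc2 and the bile acid conjugating enzyme gene Baat, at -0.16 (SE 0.091), being the named lower members. The count stayed at 2 without mthr-/- 1, whose kept spots of Abcb11, Abcc3 and Abcc6 read 0.5, 0 and 0. Nitrogen metabolism had 4 of 6 genes higher, but 2 with median centring, cyclic loess or slide series as a block (adjusted p = 0.742), with the amino acid carrier Slc38a4 at 0.12 (SE 0.10) and the glutaminase gene Gls2 at 0.093 (SE 0.10). Lipid metabolism had 2 of 6 higher, but 5 without normalization or with reference gene centring (adjusted p = 0.766), with Apoa1, the main protein of high-density lipoprotein, at 0.89 (SE 0.54). Apoa1 stood at -0.042 (SE 0.51) with slide series as a block and at 0.57 without wild type 6. Acute phase had 2 of 3 genes higher (adjusted p = 0.372), with Serpina3n and the adhesion molecule gene Vcam1 at 0.023 (SE 0.038). Hepatocyte markers had 3 of 4 higher, but 0 with slide series as a block (adjusted p = 0.585), with Apoa1 and the fatty acid binding protein gene Fabp1 at -0.60 (SE 0.54), the latter near background in the kept spots of mthr-/- 1 and at -0.12 without that array. Stellate cell and fibroblast markers had 1 of 4 higher, but 4 without normalization or with reference gene centring (adjusted p = 0.506), with the collagen gene Col3a1 at -0.070 (SE 0.055) and the fibronectin gene Fn1 at 0.072 (SE 0.17). Common reference genes had 2 of 4 higher, but 0 with median centring (adjusted p = 0.372), with the glycolytic gene Gapdh at -0.34 (SE 0.23), at -0.21 without wild type 6 and at 0.0020 (SE 0.22) with slide series as a block. Without mthr-/- 1, whose kept spots of Apoc3 and Arg1 were near background, lipid metabolism had 3 of 6 and nitrogen metabolism 5 of 6 genes higher. Other counts that moved by over 1.5 times without 1 array were those of protein folding, 3 without wild type 1 or mthr-/- 5, of lipid metabolism, 1 without mthr-/- 2, of stellate cells, 2 without wild type 1, mthr-/- 5 or mthr-/- 6 and 0 without mthr-/- 3, and of reference genes, 1 without wild type 6, mthr-/- 3, mthr-/- 5 or mthr-/- 7. In each of these 9 lists 0 genes passed the threshold over all genes and 0 when adjusted over the list alone. Genes with several tested oligonucleotides had the same sign in Ahcy, Cbs and Csad, while the dimmer one of Ctsb was at -0.013 (SE 0.031) against 0.19 (SE 0.18) for the brighter.

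Directions depended on the scaling. The median of all 134 genes shifted by 0.61 when arrays were centred on reference genes and by 0.82 without normalization. The counts of higher genes per list under these 2 settings include that shift. For the bile acid genes 7 of 7 were higher under both. Only 2 of the 7 lay above the median of all genes there, as with quantile normalization. Ahcy and Mt1 stayed higher under each of the 4 other scalings, whereas Cdo1 and Sord turned to -0.15 and -0.011 with median centring. Of the 8 lower genes 5 turned positive with reference gene centring and 6 without normalization.

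A few arrays stood apart in single genes. On mthr-/- 1 the kept spots of Fabp1 and of the lipid and nitrogen genes Apoc3, Apoh, Apoc4, Apoa5 and Arg1 were near background, with intensities of 18 and 22 for Fabp1 in blocks 2 and 4, against 3658 in block 1, which the authors blanked. Of the 22 spots blanked in block 1 there, 19 lay between array positions 26 and 92. In that range Aqp8 and the bile genes Abcb11, Abcc3 and Abcc6 read 0, 0.5, 0 and 0 on this array. The bile genes Abcc2 and Abcc4 of that range read 14 and 7.67. The muscle genes Mb, titin cap and Slc25a4 had intensities of 360, 327 and 242 on mthr-/- 6, against at most 32.8, 49.8 and 22 on the 12 arrays other than wild type 6 and mthr-/- 6, and titin cap and Slc25a4 stood at 164 and 263 on wild type 6. Leaving out these 3 arrays, a choice made after seeing the data, limma called 0 genes for genotype, with 4 at an unadjusted p below 0.05. With slide series as a block in addition it called 1 gene, lower in mthr-/-.

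**Figure D3:**
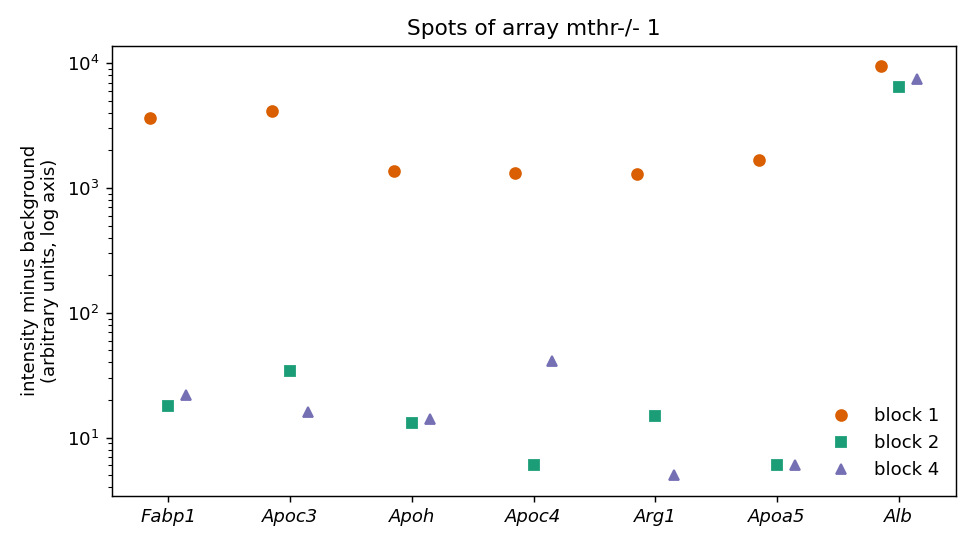
Background-subtracted intensity, in arbitrary units on a log axis, of 7 genes on array mthr-/- 1 in block 1, block 2 and block 4, with a mark for each spot; values for block 3 repeat block 2 and are left out. Fabp1 reads 3658, 18 and 22, while albumin (Alb), at another position, reads 9428, 6457 and 7484.

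Slide series was a further difference between the arrays. With genotype in the model, 7 genes differed between series A and series B in limma. Higher in series A were Bhmt by 1.53 (SE 0.29, adjusted p = 0.0151), Ahcy by 0.58 (SE 0.13, adjusted p = 0.0389), the lysosomal protein gene Psap by 0.43 (SE 0.076), Rps2 by 0.57 (SE 0.11), Slc38a4 by 0.35 (SE 0.082) and the adenosine kinase gene Adk by 0.21 (SE 0.053). The ribosomal protein gene Rpl30 differed by -0.57 (SE 0.14). This comparison, and the genes named in it, were chosen after the genotype result had been seen. In the authors' deposited table the median of mthr-/- over that of wild type was 8.47 for Mt1, 6.27 for Bhmt, 5.49 for Psap, and 5.19 and 3.22 for the 2 oligonucleotides of Ahcy. These are ratios of medians of scaled intensities, a measure unlike the normalized differences above, where Mt1 was 1.95-fold and Ahcy 1.45-fold. With an offset of 0 Mt1 was 2.39-fold and Ahcy 1.78-fold. For Psap the wild type median behind the ratio was only 6.02. The authors' deposited table lists 17 of 103 ratios at 2 or more and 1 at 0.5 or less.

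Between 6 females and 8 males, with genotype in the model, limma called 0 of 134 genes, the smallest adjusted p was 0.9997, and 3 genes had an unadjusted p below 0.05. These were G6pc, the last enzyme of glucose release, at 0.43 higher in females (SE 0.15), the bile acid carrier gene Slc10a1 at 0.29 (SE 0.12) and the ribosomal protein gene Rpl3 at 0.14 (SE 0.055), named after their values were seen. Whether the genotype difference depended on sex was tested with an interaction term, which called 0 genes in limma (smallest adjusted p = 0.996). There 2 genes had an unadjusted p below 0.05, Cth at -0.51 (SE 0.22) and the insulin receptor gene Insr at 0.23 (SE 0.10), as females minus males, also named after their values were seen. The wild type group holds only 2 females, which widens these errors.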

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

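All tests of explanations in this part, and the counts over splits, were chosen after the results were seen.

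In 90 groups of 7 values, 14 held a highest or lowest array whose gap to the rest was large against the range, where chance gives about 1 in 20. Wild type 6 stood apart in 5 genes. There Chdh was at 6.60, Fn1 at 6.79, Rps3a1 at 7.03, Pemt at 7.09 and Sord at 7.19, all below the other wild type arrays. On wild type 1 Bhmt at 8.81 and Slc38a4 at 7.36 were high, and Dmgdh at 7.01 and Shmt1 at 6.81 were low. On mthr-/- 4 Hspe1 at 8.04 and Serpina3n at 7.88 were high. Low values were Fabp1 at 6.94 on mthr-/- 1 and Abcc2 at 6.62 on mthr-/- 3, and Col3a1 at 7.00 on mthr-/- 7 was high. Background-subtracted intensity was -1890 for Abcc2 on mthr-/- 3 and -10.5 for Chdh on wild type 6. Local background exceeded the signal there, so these 2 values do not show a low level. Fn1 at 1.75 and Rps3a1 at 9.25 were below the limit of 9.81 on wild type 6. Shmt1 at 3.75 was below the limit of 7.03 on wild type 1. The levels of these 3 genes were therefore not measured there. Fabp1 on mthr-/- 1 rests on the kept spots near background described above.

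The 16 tested genes with an oligonucleotide that the authors' deposited table lists at 2-fold or more, which were picked on these samples and are taken here by the brightest such oligonucleotide, were 0.24 (log2, 95% interval -0.03 to 0.50) higher in mthr-/- on average. With slide series as a block the difference was 0.031 (-0.09 to 0.15), and wild type 1, the wild type array of series A, stood at 7.61, above the 6.96 to 7.08 of the wild type arrays of series B, so slide series may account for most of it. The authors' values of wild type 1 are blank for Bhmt, Psap, Cps1 and an oligonucleotide of Cbs, which read 213, 75.3, 205 and 79.3 there. Brightness of the arrays cannot be told apart, since with summed intensity as a covariate the difference was 0.21 (-0.08 to 0.50), though the mthr-/- arrays of series A still exceeded the other mthr-/- arrays by 0.38 (SE 0.053). An effect of genotype itself stays open, since the difference within series B was 0.11 (-0.01 to 0.24) on 6 arrays, an interval that spans both 0 and the pooled value, that within series A was -0.11 (-0.34 to 0.12) but rests on 1 wild type array, and betaine in the water is confounded with genotype.

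Fabp1, Apoc3, Apoh, Apoc4, Arg1 and Apoa5 were low on mthr-/- 1, by -2.45 on average against the other mthr-/- arrays. Genotype is argued against, since the other 6 mthr-/- arrays differed from wild type by 0.055 (-0.28 to 0.38). In block 1, whose spots of these genes the authors blanked, the genes lay at 1.06, against -2.47 and -2.46 in blocks 2 and 4, so the low values may follow from which spots were kept. Between array positions 33 and 85, 7 other oligonucleotides were bright in block 1, and 6 read under 0.2 of that in both other blocks. Elsewhere 1 of 55 did (Fisher's exact test, p = 7.85e-07, with neighbouring spots of 1 slide taken as independent). This goes with a stretch of positions lost in those blocks. Since brightness in block 1 was the criterion, the count cannot tell such a loss from excess signal in block 1. Atp1b1, among the 6, read 296, 0 and -1 in blocks 1, 2 and 4, against at most 52.5 on the other arrays. An earlier form of the test for a lost stretch, on normalized values, found 0 of 12 and counted against it, although only 2 of the 12 had room to fall by 1.

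Mb, titin cap and Slc25a4, genes abundant in muscle, were high on mthr-/- 6, and the last 2 on wild type 6. Normalization of a dim array is argued against for titin cap and Slc25a4 on wild type 6, whose summed intensity was 14944. Before normalization these 2 of 2 genes exceeded the 12 arrays other than wild type 6 and mthr-/- 6. Mb was left out of that count. On wild type 6 it exceeded those 12 arrays after normalization, at 7.27 against at most 6.99, but not before, at 18 against 32.8. For Mb there this explanation stays open. The summed intensity of mthr-/- 6, at 73587, was not dim. RNA from muscle might be a source, but of 8 other muscle genes above background on at least 1 array 4 had their highest intensity on one of these arrays, a count between the limits set for and against it, so it cannot be told apart from other sources. The 4 were Myh7 at 65 and 84.8 and Ak1 at 114 and 56.8 on wild type 6 and mthr-/- 6, and skeletal actin at 31.5 and Ankrd2 at 13.3 on mthr-/- 6, against at most 3.5 and 4 on the 12 arrays, while Nppa, Ryr1 and Slc2a4 were above background on 13, 6 and 8 arrays, Atp2a2 stayed near background, Mb itself read 18 on wild type 6, and a second oligonucleotide of Mb read 1 on mthr-/- 6. That second oligonucleotide of Mb was above background on only 3 arrays and read at most 9.5 on any, so its reading decides nothing. No biological explanation was tested, since wild type 6 and mthr-/- 6 belong to different genotypes.

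Regrouping the 14 arrays does not exclude chance for any count. For genes below an unadjusted p of 0.05, 19 of 100 splits gave at least the real 10, with 29 in the highest other split. Of the 5 splits with the most such genes, each put 4 or all 5 arrays of series A on one side. How often the other splits do so was not counted. Since 4 of these 5 arrays are mthr-/-, the pattern cannot tell slide series from genotype. With slide series as a block the genotype count was 1. For genes past the adjusted threshold between the genotypes, genes between the sexes and lists between the genotypes, the real count was 0 and 100 of 100 splits gave as many, which any count of 0 must; the highest other was 1 in each case.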

How the results depend on the processing

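The settings that leave out the 3 arrays that stood apart, centre the blocks, keep the blanked spots, use the first block of mthr-/- 1 alone or join an offset of 0 with slide series as a block were chosen after the genotype result was seen. Under all settings run the genotype count was 0 genes in limma, with 2 exceptions. Without normalization it was 1, Mt1 at 1.59 (adjusted p = 0.0223), in a setting that shifts the median of all genes by 0.82. Without the 3 arrays and with slide series as a block it was 1 gene, lower in mthr-/-, and without the 3 arrays alone it was 0; the cause was not tested. The smallest adjusted p ran from 0.00751 to 0.958 over the alternatives. Counts at an unadjusted p below 0.05 moved more: 10 of 134 as reported, 1 with slide series as a fixed block, 2 as a random block, 20 with array weights, 6 with median centring, 18 of 272 without the filter, 12 of 99 with the authors' values, 64 without normalization and 66 with reference gene centring. Leaving out one array gave 0 called genes each time, and from 4 (without mthr-/- 3) to 24 (without wild type 1) unadjusted, with 5 without wild type 6, wild type 7 or mthr-/- 4 and 6 without mthr-/- 1. Within series A the lone wild type array is taken to vary like the rest. Sex and interaction gave 0 in all settings run, with 0 to 5 and 0 to 2 unadjusted, and lists gave 0, with 0 to 2.

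No call existed to be lost, so a change of sign in a gene past the threshold in neither setting was counted as a turn. Of the 46 named genes, 8 kept their sign in every setting apart from single arrays left out, 41 in each leave-one-out fit and 35 with slide series as a block. Of the 43 reported here, 29 moved by over 1.5 times or turned in at least 1 leave-one-out fit. Animal numbers did not pair the arrays, since 4 of 7 correlations of deviations exceeded 0.1 and 0 animals correlated best with their own number. With the animal number as a replicate block 0 genes and 0 lists were called. Scan date and scanner setting were not run as blocks, since the sources used here give none. Signal over background limits the dim genes: 134 of 272 were tested. Wild type 6 had 70 oligonucleotides above background, under a limit of 9.81 that was the highest of the arrays. In the simulated arrays 67.5% of true log2 changes of 1 were called, with no effect of slide series in the simulation and a spread between spots that was set, not estimated.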

Other observations

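Levels within mthr-/- were uneven for Mt1, the metallothionein gene. On mthr-/- 1, 4 and 5 it was at 9.55, 9.62 and 9.40 (log2 normalized intensity), on mthr-/- 2 at 8.59, and on mthr-/- 3, 6 and 7 at 7.52, 7.31 and 7.56, within the wild type range of 6.89 to 8.61. The 3 highest are 2 females of series A and 1 male of series B. The gene was picked after its values were seen, and no test was run on this split.

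A transcript described in the files as similar to alpha-1-B glycoprotein, picked after its values were seen, also varied widely. In the 2 wild type females it was at 8.76 and 8.83, and in the wild type males between 6.72 and 7.91. In mthr-/- it was at 9.58 and 9.36 in 2 females, at 7.17 and 7.11 in the other females, and at 9.11, 7.87 and 6.81 in the males. The difference of females minus males was 0.95 (SE 0.52) and did not pass limma (adjusted p = 0.9997). The 4 highest mthr-/- values are those of series A. The sex labels could not be checked with the gene lists, since 0 genes of the male-biased and 0 of the female-biased list were found on the array by name. The transcript described here had no matched gene name.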
